A study of Homo sapiens with 47 samples.

How the data were processed

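RNA of paraffin-embedded skin and kidney biopsies had been extracted with a paraffin RNA kit (Roche), amplified to biotinylated cRNA (Ambion MessageAmp) and hybridised to Illumina expression arrays of 47303 probes. The series holds 47 samples: 6 of chronic cutaneous lupus (CCLE), 10 of subacute cutaneous lupus (SCLE), 10 of control skin, 14 of lupus nephritis and 7 of control kidney. Expression values were used for 46 arrays, 25 of skin and 21 of kidney. The deposited table holds processed log2 expression values that the authors made with lumi per the submitters' processing notes, with no version given. They range from 6.83 to 16.24 with a median of 7.68, and their normalization is not stated in the labels. In the deposited table the column of CCLE replicate 1 holds values from 0 to 1, read as detection p-values, in place of expression values, so that CCLE has n = 5 with values, and they are described only in the closing section. A deposited table of scanner output has 102 columns named in a way that no sample label holds. Its columns were not used here.

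The plan made before the data were examined was to normalize scanner signals with neqc in limma. That needs scanner signals per sample, so the deposited log2 values were used instead, and background was set on them. Detection p-values were not used for the filter. A value of 8 was taken as background after the distribution of all values had been seen. A probe was kept when it lay above 8 in at least 5 skin arrays or at least 7 kidney arrays, the size of the smallest group of the tissue. The share of probes above 8 per array is given as the share above background, and the number of arrays limits the precision of every value. Probes were named from the array's annotation: 30102 had 1 gene symbol, 8 had several and 17193 were left unnamed, and 30063 were matched to the reference by their gene identifier. The 143 probes of XIST and Y-linked genes were left out. For a gene with several probes the one with the highest mean over the arrays of the fit was taken. A probe below 8 in every array of a group was given only as a bound.

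Groups were compared with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8) by lmFit and eBayes with trend, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. The 3 skin groups shared 1 fit and the kidney groups another. The difference of the lupus effect between kidney and skin was tested in 1 fit with 5 group means over the 46 arrays, among genes that passed the filter in both tissues. Overlaps of genes in skin and kidney came from that fit. The 34 gene lists, fixed before the data were examined together with the comparisons, tests and most alternatives, hold 544 genes, of which 508 had a probe. They are type I interferon-stimulated genes, interferon-gamma response genes, MHC class II genes, cytotoxic lymphocyte markers, T cell markers, B cell and plasma cell markers, monocyte and macrophage markers, plasmacytoid dendritic cell markers, neutrophil markers, mast cell markers, endosomal Toll-like receptor pathway, Fas and death receptor apoptosis genes, inflammasome genes and complement genes. Basal keratinocyte markers, differentiated keratinocyte markers, stressed keratinocyte genes, hair follicle markers, sweat and sebaceous gland markers, melanocyte markers, adipocyte markers, endothelial markers, smooth and striated muscle markers and extracellular matrix genes mark the skin and its stroma. Podocyte markers, proximal tubule markers, thick ascending limb and distal tubule markers, collecting duct markers, tubular injury genes, cell cycle genes, immediate early genes, oxidative phosphorylation genes, cytosolic ribosomal protein genes and erythrocyte markers complete them. Each list was tested with camera (preset correlation 0.01, and estimated per list as an alternative), adjusted over the 34 lists within a comparison.

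After the data had been seen, the mean of each list per array was also compared by two-sided permutation tests, exact where a group had fewer than 10 arrays and otherwise with 100000 resamples. As planned, the likeness of CCLE and SCLE effects was set against simulated unchanged groups and against divided controls. Named genes followed a rule made before the data were examined: the 8 largest changes per direction past the threshold, up to 4 members per list that passed (the text names the first 2 by p, and further ones where useful), and a fixed set of interferon, T cell, complement and kidney genes. Some genes of that set are not reported here. For the difference between tissues the 5 largest per direction were named. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The alternatives were no filter or a filter that needs every array of a group above background, every probe, eBayes without trend, array weights, the share above background as a covariate and leaving out arrays more than 3 MAD below the tissue's median share. Further ones were the replicate number as a block, only the groups compared, a minimum change, leaving out each array, and, chosen after the data had been seen, quantile normalization within tissue, a separate fit per tissue for the overlap, leaving out SCLE 8, 9 and 10, and several of these for lists, overlaps and the likeness of CCLE and SCLE.

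The fits were tested on simulated data in which 200 genes of known change were placed among unchanged ones. With a spread shared by the groups, the kidney fit called 52 genes, 5 of them unchanged, and recovered 53% of changes of 2 on the log2 scale. The CCLE fit called 106 with 6 unchanged and recovered 97.0%. With each group's own spread, as in the real arrays, CCLE against control skin called 99 with 6 unchanged, SCLE 139 with 15 unchanged, and CCLE against SCLE 107 with 13 unchanged. The kidney fit called 348 with 278 unchanged, and 70 with 49 unchanged under array weights. The fit of the difference between tissues called 452 with 389 unchanged, and 101 with 87 unchanged under array weights. With so few changes, kidney fits exceeded their nominal error rate.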

Results

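The data comprised gene expression arrays of RNA from paraffin-embedded biopsies of skin and kidney. Expression values were used for 46 arrays: 5 of chronic cutaneous lupus (CCLE), 10 of subacute cutaneous lupus (SCLE), 10 of control skin, 14 of lupus nephritis and 7 of control kidney. The share of probes above background averaged 45.5% (SD 0.231) in CCLE, 44.7% (SD 0.880) in SCLE, 45.2% (SD 0.722) in control skin, 45.1% (SD 0.652) in lupus nephritis and 34.8% (SD 6.91) in control kidney. The share did not differ detectably between skin groups. It was 0.33 percentage points higher in CCLE than in control skin (exact permutation test, two-sided, p = 0.348, adjusted p = 0.348) and 0.75 higher in CCLE than in SCLE (exact permutation p = 0.0716, adjusted p = 0.143). The difference of SCLE from control skin was -0.42 (permutation p = 0.264, adjusted p = 0.348). Lupus nephritis arrays exceeded control kidney arrays by 10.3 percentage points (exact permutation p = 9.46e-05, adjusted p = 0.000378). Of the 7 control kidney arrays, 6 lay at 41.5% or below, and kidney control 6 lay at 45.5%.

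**Figure D1:**
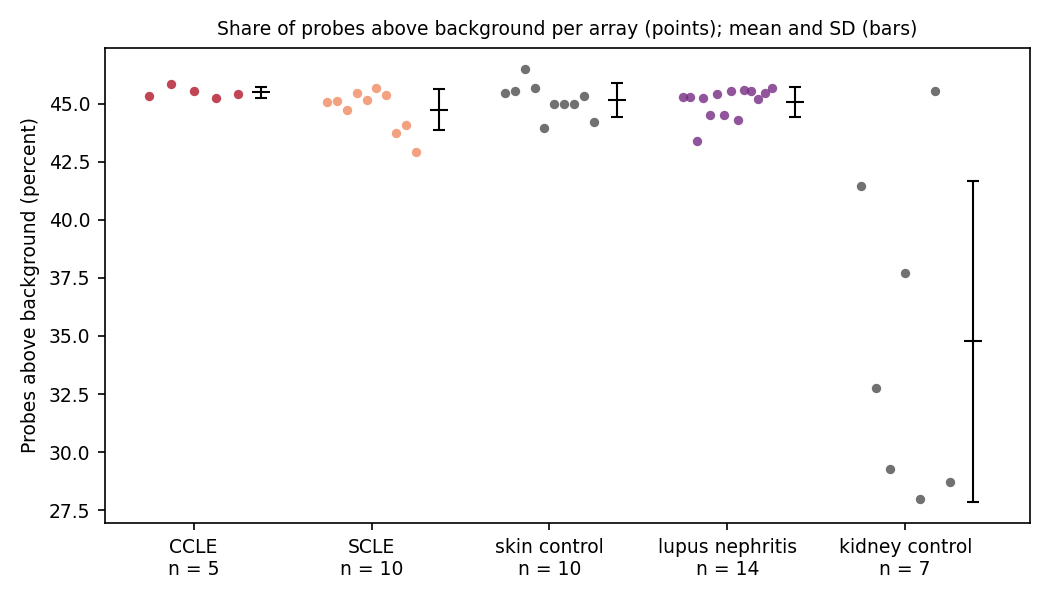
Share of probes above background (percent, vertical axis) per array, by group, with 1 point per array and bars for the mean and SD over arrays. Skin and lupus nephritis arrays lie between 42.9% and 46.5%, and control kidney arrays spread from 28% to 45.5%.

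CCLE skin (5 arrays) had more interferon-stimulated transcripts than control skin (10 arrays). Type I interferon-stimulated genes (33 of 33 measured), cytotoxic lymphocyte markers (13 of 14), B cell and plasma cell markers (11 of 14) and plasmacytoid dendritic cell markers (8 of 8) were higher, and these lists also passed with an estimated correlation (adjusted p from 0.00346 to 0.0232). T cell markers (14 of 20) and stressed keratinocyte genes (13 of 16) were higher, and melanocyte (9 of 9), hair follicle (4 of 12), gland (2 of 15), adipocyte (3 of 9) and matrix genes (8 of 20, with 1 higher) lower. The calls of these 7 lists were lost with an estimated correlation (adjusted p from 0.0873 to 0.277). Per array, the type I interferon-stimulated genes averaged 13.75 (SD 0.15) in CCLE and 11.54 (SD 0.19) in control skin, a difference of 2.21, and all 5 CCLE arrays lay above every control array (exact permutation test, two-sided, p = 0.000333, the smallest it can give, adjusted p = 0.00103). Of 15198 genes tested with limma, 2926 passed an adjusted p of 0.05, 1569 higher and 1357 lower, and 1667 of them had an absolute log2 fold change of at least 1 (863 higher, 804 lower). The largest increases, as log2 fold changes with standard errors, were those of CXCL10 (5.35, SE 0.58), a chemokine that draws T cells, APOBEC3A (5.25, SE 0.47), a cytidine deaminase, and the interferon-stimulated gene OASL (4.88, SE 0.30). KLHDC7B (4.70), RSAD2 (4.62), CMPK2 (4.44) and CXCL11 (4.43) and the cornified envelope gene LCE3A (4.42) followed (adjusted p from 3.35e-11 to 0.00177 over these 8 genes). CXCL11 was above background in 1 of the 10 control arrays, CXCL9 and FASLG in 2, PTCRA and S100A12 in 3, and, among the decreases, LPL in 1 of 5 CCLE arrays and AWAT2, CAPN13 and TNMD in 2.

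Interferon-stimulated genes rose throughout. All 33 type I interferon-stimulated genes measured were higher (33 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 2.06 (list adjusted p = 1.04e-47, and adjusted p = 0.00346 with an estimated correlation). OASL and IFIT3 (3.82, adjusted p = 1.88e-10) had the smallest p of the list, IFI44L rose by 2.94 and IFI27 by 2.00, and MX1, already near the top of the scale in control skin, rose by 0.24 (adjusted p = 0.0309). Interferon-gamma response genes (21 measured, 18 higher, 0 lower and 3 not passed) had a median of 2.16 (adjusted p = 3.47e-20), with CXCL11 (4.43), BATF2 (4.21) and CXCL9 (2.64) among them. Interferon-gamma response genes had 20 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.00670. MHC class II genes, which present antigen to helper T cells, rose (10 measured, 6 higher, 0 lower and 4 not passed, median 0.48, adjusted p = 0.000261), with HLA-DOB (1.27) and their activator CIITA (1.09). MHC class II genes had 7 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.125. The endosomal Toll-like receptor pathway, which senses nucleic acids, rose (13 measured, 7 higher, 0 lower and 6 not passed, median 0.93, adjusted p = 6.82e-06), with IRF7 (1.35) and TASL (2.93). The endosomal Toll-like receptor pathway had 8 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.0249. Genes of the Fas and death receptor pathway (12 measured, 8 higher, 0 lower and 4 not passed, median 1.2, adjusted p = 1.23e-07) included ZBP1 (3.99), MLKL (1.42) and FASLG (1.94, adjusted p = 0.000260). The Fas and death receptor apoptosis genes had 8 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.00440. Inflammasome genes rose (12 measured, 6 higher, 0 lower and 6 not passed, median 0.97, adjusted p = 1.02e-05), with AIM2 (1.96) and IFI16 (1.24), whereas IL18 did not pass (-0.02, adjusted p = 0.950). Inflammasome genes had 9 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.00603.

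Cytotoxic lymphocyte markers (14 measured, 13 higher, 0 lower and 1 not passed) had a median of 2.03 (adjusted p = 3.05e-12), with CCL5 (2.29), GNLY (2.96) and GZMB (2.69, adjusted p = 0.00371). Cytotoxic lymphocyte markers had 14 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.0232. T cell markers (20 measured, 14 higher, 0 lower and 6 not passed) had a median of 1.41 (adjusted p = 1.26e-09), with CTLA4 (2.21), CD8B (2.38) and CD8A (2.27, adjusted p = 0.0176). T cell markers had 17 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.109. B cell and plasma cell markers (14 measured, 11 higher, 0 lower and 3 not passed) had a median of 2.48 (adjusted p = 2.48e-12), with CD38 (3.85) and POU2AF1 (3.68). B cell and plasma cell markers had 11 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.0152. Plasmacytoid dendritic cell markers, those of the cells that release much type I interferon (8 measured, 8 higher, 0 lower and 0 not passed), had a median of 2.34 (adjusted p = 4.75e-09), with PTCRA (2.85) and PLAC8 (3.53). Of the plasmacytoid dendritic cell markers, 8 were higher and 0 lower adjusted over the list alone, and with an estimated correlation adjusted p = 0.0209. Monocyte and macrophage markers (18 measured, 11 higher, 0 lower and 7 not passed) had a median of 0.94 (adjusted p = 4.75e-09), with C1QC (1.31), FCGR3A (2.53, another probe near background -0.18) and C1QB (1.64). Monocyte and macrophage markers had 13 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.0152. Neutrophil markers (12 measured, 7 higher, 1 lower and 4 not passed, median 0.89, adjusted p = 0.00111) rose with S100A12 (2.95) and FPR1 (2.73). Neutrophil markers had 7 higher and 2 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.0624. Complement genes split (16 measured, 6 higher, 4 lower and 6 not passed, median 0.40, adjusted p = 0.00917), and CFB (2.47) was among the higher. Complement genes had 7 higher and 4 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.108. Mast cell markers fell (8 measured, 0 higher, 3 lower and 5 not passed, median -0.59, adjusted p = 0.00342), with KIT (-1.81) and CPA3 (-1.61). Mast cell markers had 0 higher and 5 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.108.

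Stressed keratinocyte genes (16 measured, 13 higher, 0 lower and 3 not passed) had a median of 2.04 (adjusted p = 1.61e-10), with IL36G (1.42) and SPRR1B (1.96). Stressed keratinocyte genes had 15 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.0873. Cell cycle genes rose (17 measured, 6 higher, 0 lower and 11 not passed, median 0.50, adjusted p = 0.000796), with RRM2 (1.07) and MKI67 (0.85). Cell cycle genes had 9 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.179. Melanocyte markers fell in all 9 genes measured (0 higher and 9 lower adjusted over the list alone, median -1.91, adjusted p = 8.08e-07, but adjusted p = 0.108 with an estimated correlation), with PMEL (-2.30) and MLANA (-3.30). Hair follicle markers (12 measured, 0 higher, 4 lower and 8 not passed, median -2.13, adjusted p = 0.000415) fell with KRT72 (-2.48) and the stem cell gene LGR5 (-2.03). Hair follicle markers had 0 higher and 9 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.179. Sweat and sebaceous gland markers (15 measured, 0 higher, 2 lower and 13 not passed, median -0.94, adjusted p = 0.00137) fell with FA2H (-2.0) and AWAT2 (-2.33). Sweat and sebaceous gland markers had 0 higher and 5 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.251. Adipocyte markers (9 measured, 0 higher, 3 lower and 6 not passed, median -1.65, adjusted p = 0.00119) fell with THRSP (-3.01) and LPL (-1.24). Adipocyte markers had 0 higher and 4 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.220. Extracellular matrix genes (20 measured, 1 higher, 8 lower and 11 not passed, median -0.67, adjusted p = 0.00119) fell with SPARC (-1.46) and THBS2 (-0.73). Extracellular matrix genes had 1 higher and 10 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.277. Erythrocyte markers (7 measured, 0 higher, 4 lower and 3 not passed, median -1.28, adjusted p = 0.00111) fell with HBB (-3.47) and AHSP (-2.26). Erythrocyte markers had 0 higher and 5 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.111. Outside the lists the largest decreases were UGT3A2 (-4.09), TNMD (-3.73), GSTM5 (-3.70), IL17D (-3.57), CAPN13 (-3.55), NNAT (-3.39) and MRAP (-3.37) (adjusted p from 2.73e-05 to 0.00518).

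Of the 34 gene lists, 22 passed in CCLE against control skin, 15 upwards and 7 downwards, and 9 of them with an estimated correlation. Among those that did not, with median log2 fold change and adjusted p, were basal keratinocyte markers (0.09, 0.920), differentiated keratinocyte markers (0.09, 0.224), endothelial markers (-0.09, 0.372), smooth and striated muscle markers (-0.73, 0.0554), podocyte markers (-0.21, 0.386) and proximal tubule markers (-0.48, 0.0607). Nor did the other 6 (medians from -0.27 to 0.02, adjusted p from 0.191 to 0.956) pass, and for the thick ascending limb list the mean (0.05) had the opposite sign to the median and the test. Permuting the arrays, the mean of a list per array differed for 24 lists (15 higher, 9 lower). Nothing in the labels says that the samples of a group came from separate donors, so p-values measure the spread between samples. The count of genes depended on single arrays (1831 without CCLE 6) and on weights (5821).

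In SCLE skin (10 arrays) type I interferon-stimulated genes (31 of 33 measured), cytotoxic lymphocyte markers (11 of 14) and T cell markers (13 of 20) were higher than in control skin (10 arrays), calls lost with an estimated correlation (adjusted p from 0.0507 to 0.321). Gland (11 of 15), hair follicle (8 of 12), mast cell (6 of 8) and matrix genes (9 of 20, with 2 higher) were lower, calls also lost with an estimated correlation (adjusted p from 0.238 to 0.510). The type I interferon-stimulated genes averaged 13.32 (SD 0.38) in SCLE and 11.54 (SD 0.19) in control skin, a difference of 1.78, and all 10 SCLE arrays lay above every control array (permutation test, two-sided, p = 2e-05, adjusted p = 0.000227). Of 15198 genes, 7344 passed, 3291 higher and 4053 lower, and 2847 of them (1155 higher, 1692 lower) had an absolute log2 fold change of at least 1. The largest increases were those of CXCL10 (4.79, SE 0.47), APOBEC3A (4.60, SE 0.38) and OASL (4.48, SE 0.25), followed by KLHDC7B (4.05), BATF2 (3.93), RSAD2 (3.91), CMPK2 (3.90) and CXCL11 (3.81) (adjusted p from 3.60e-12 to 5.56e-08). The largest decreases were UGT3A2 (-4.41), MRAP (-4.00), IL17D (-3.52), CAPN13 (-3.36), GSTM5 (-3.32), LARP6 (-3.27), HAO2 (-3.21) and SCGB2A1 (-3.18) (adjusted p from 1.82e-06 to 0.000647). In SCLE, KRT25 and TYRP1 were above background in 2 of 10 arrays, UGT3A2 and SCGB2A1 in 3, CAPN13 in 4, MRAP and LARP6 in 5.

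Type I interferon-stimulated genes in SCLE (33 measured, 31 higher, 0 lower and 2 not passed) had a median log2 fold change of 1.57 (adjusted p = 3.18e-28), with IFIT3 (3.50), IFI44L (2.65), IFI27 (1.75) and MX1 (0.37, adjusted p = 0.000138). Of the type I interferon-stimulated genes, 31 were higher and 0 lower adjusted over the list alone, and with an estimated correlation adjusted p = 0.0507. Interferon-gamma response genes (21 measured, 17 higher, 0 lower and 4 not passed, median 1.81, adjusted p = 3.63e-13) included GBP1 (3.16) and CXCL9 (2.70). Interferon-gamma response genes had 17 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.0605. Cytotoxic lymphocyte markers (14 measured, 11 higher, 0 lower and 3 not passed, median 1.83, adjusted p = 9.54e-08) included CCL5 (1.85), PRF1 (2.95) and GZMB (1.70, adjusted p = 0.00872). Cytotoxic lymphocyte markers had 12 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.158. T cell markers (20 measured, 13 higher, 0 lower and 7 not passed, median 1.28, adjusted p = 1.24e-05) included CTLA4 (2.5), CD8B (3.00) and CD8A (1.41, adjusted p = 0.0346). T cell markers had 13 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.321. B cell and plasma cell markers (14 measured, 7 higher, 0 lower and 7 not passed, median 0.72, adjusted p = 0.00567) included CD38 (2.94) and POU2AF1 (1.79). B cell and plasma cell markers had 7 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.374. Plasmacytoid dendritic cell markers (8 measured, 6 higher, 0 lower and 2 not passed, median 1.11, adjusted p = 0.00297) included PTCRA (1.87) and PLAC8 (2.58). Of the plasmacytoid dendritic cell markers, 6 were higher and 0 lower adjusted over the list alone, and with an estimated correlation adjusted p = 0.285. Monocyte and macrophage markers (18 measured, 11 higher, 0 lower and 7 not passed, median 0.82, adjusted p = 0.000387) included FCGR3A (2.56, another probe near background -0.32), LILRB2 (2.14) and C1QB (1.03). Monocyte and macrophage markers had 11 higher and 1 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.187.

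MHC class II genes in SCLE (10 measured, 9 higher, 0 lower and 1 not passed, median 0.67, adjusted p = 0.000488) rose with CTSS (0.96) and HLA-DPA1 (0.47). MHC class II genes had 9 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.251. The Fas and death receptor list (12 measured, 9 higher, 0 lower and 3 not passed, median 1.01, adjusted p = 0.000479) rose with ZBP1 (2.77) and FASLG (1.74). Fas and death receptor apoptosis genes had 9 higher and 1 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.0605. The endosomal Toll-like receptor pathway (13 measured, 8 higher, 1 lower and 4 not passed, median 0.67, adjusted p = 0.00297) rose with IRF7 (0.95) and TASL (1.85). The endosomal Toll-like receptor pathway had 8 higher and 1 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.226. Inflammasome genes (12 measured, 7 higher, 1 lower and 4 not passed, median 0.63, adjusted p = 0.00573) rose with AIM2 (1.54) and PYCARD (1.64, another probe -0.01), whereas IL18 did not pass (0.00, adjusted p = 0.987). Inflammasome genes had 7 higher and 1 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.112. Neutrophil markers (12 measured, 5 higher, 0 lower and 7 not passed, median 0.42, adjusted p = 0.0369) rose with CXCR2 (1.17) and MNDA (0.88). Neutrophil markers had 5 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.285. Complement genes again split (16 measured, 7 higher, 4 lower and 5 not passed, median 0.40, adjusted p = 0.0398), with CFB (2.65) and C2 (1.62) higher. Complement genes had 9 higher and 4 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.285. Stressed keratinocyte genes (16 measured, 9 higher, 0 lower and 7 not passed, median 0.82, adjusted p = 0.00196) rose with SPRR1B (1.60) and IL36G (0.92). Stressed keratinocyte genes had 9 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.455. Cell cycle genes (17 measured, 8 higher, 0 lower and 9 not passed, median 0.41, adjusted p = 0.0258) rose with MKI67 (1.31) and RRM2 (0.91). Cell cycle genes had 8 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.455.

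Among the falling lists in SCLE, sweat and sebaceous gland markers (15 measured, 0 higher, 11 lower and 4 not passed, median -1.18, adjusted p = 0.00773) lost AWAT1 (-3.16) and MUCL1 (-1.16). Sweat and sebaceous gland markers had 0 higher and 11 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.455. Hair follicle markers (12 measured, 0 higher, 8 lower and 4 not passed, median -1.78, adjusted p = 0.0221) lost KRT74 (-2.50) and KRT25 (-2.19). Hair follicle markers had 0 higher and 8 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.455. Mast cell markers (8 measured, 0 higher, 6 lower and 2 not passed, median -0.84, adjusted p = 0.00773) lost KIT (-1.95) and CPA3 (-1.91). Mast cell markers had 0 higher and 6 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.238. Melanocyte markers (9 measured, 0 higher, 4 lower and 5 not passed, median -1.0, adjusted p = 0.0208) lost TYRP1 (-1.99) and MITF (-0.89). Melanocyte markers had 0 higher and 7 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.470. Adipocyte markers (9 measured, 0 higher, 4 lower and 5 not passed, median -1.05, adjusted p = 0.0369) lost THRSP (-2.97) and LPL (-1.10). Adipocyte markers had 0 higher and 4 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.470. Extracellular matrix genes (20 measured, 2 higher, 9 lower and 9 not passed, median -0.48, adjusted p = 0.0459) lost COL5A2 (-1.77) and SPARC (-0.97). Extracellular matrix genes had 2 higher and 9 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.510. Of the 34 lists 21 passed, 15 upwards and 6 downwards, and 0 with an estimated correlation. By permutation, 28 list means per array differed (15 higher, 13 lower). The lists that did not pass, with median and adjusted p, were basal keratinocyte markers (-0.02, 0.941), differentiated keratinocyte markers (0.08, 0.543), endothelial markers (-0.03, 0.747), smooth and striated muscle markers (-0.79, 0.110), podocyte markers (0.02, 0.747), proximal tubule markers (-0.61, 0.150) and thick ascending limb and distal tubule markers (0.18, 0.543). Nor did collecting duct markers (-0.19, 0.399), tubular injury genes (-0.47, 0.123), immediate early genes (0.12, 0.320), oxidative phosphorylation genes (-0.21, 0.0732), cytosolic ribosomal protein genes (0.17, 0.0937) and erythrocyte markers (-0.53, 0.139) pass. The podocyte list had a median of 0.02 and a mean of -0.43, and the test went down.

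**Figure D2:**
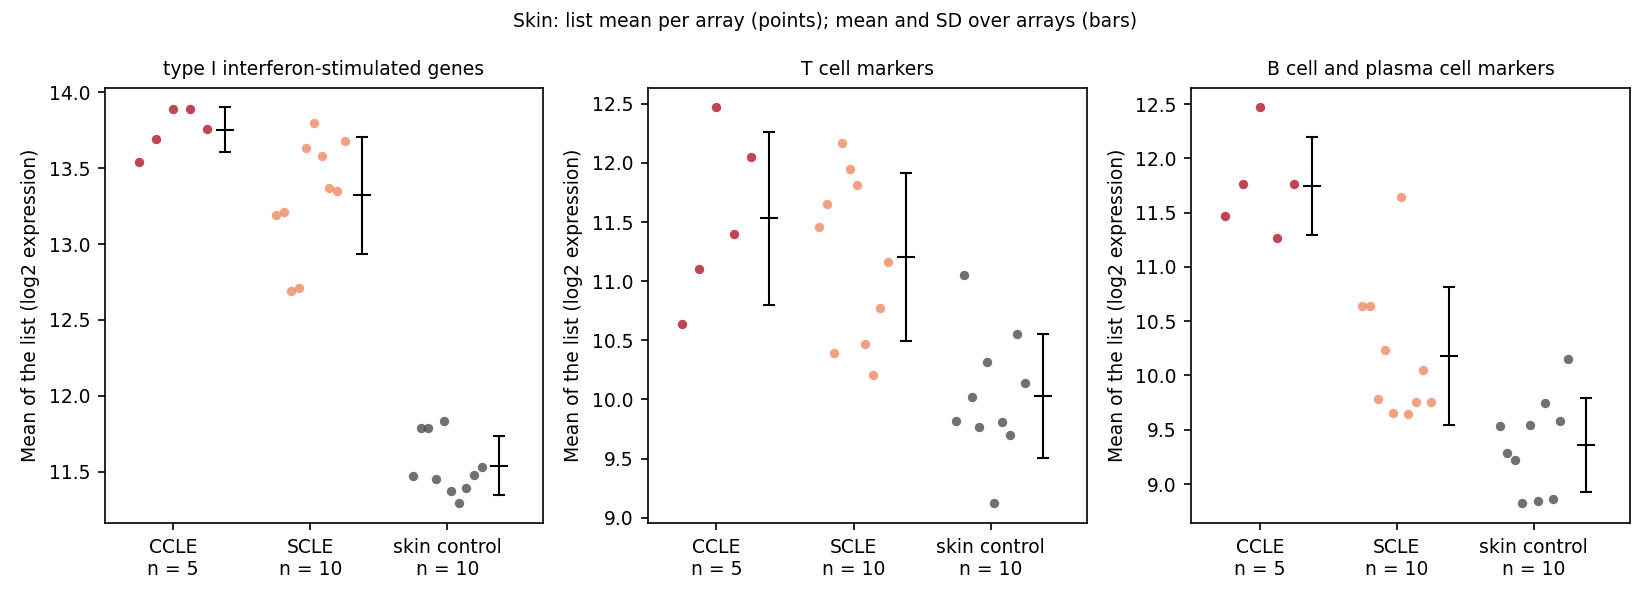
Mean log2 expression of 3 gene lists (vertical axes) per skin array, by group, with 1 point per array and bars for the mean and SD over arrays. Type I interferon-stimulated genes average 13.75 in CCLE, 13.32 in SCLE and 11.54 in control skin, T cell markers 11.53, 11.20 and 10.03, and B cell and plasma cell markers 11.75, 10.18 and 9.36.

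Across the 15198 genes, log2 fold changes of CCLE and SCLE moved alike. Both comparisons use the same control arrays, so part of the likeness is built in, and genes are not independent replicates. Over 1000 simulations with unchanged groups against shared controls, r averaged 0.395 (95% of simulations from -0.169 to 0.804), against 0.812 observed. The covariance, 0.487, lay outside the simulated range (mean 0.037, from -0.012 to 0.115), and the observed value exceeded the simulated mean by 0.450. With the control arrays divided into 5 and 5 in each of 252 ways, so that no control was shared, r averaged 0.731 (0.502 to 0.834) and the covariance 0.456 (0.354 to 0.494). Genes higher in both groups numbered 1293, where independence gives 339.8 and divided controls from 609 to 1058. Genes lower in both numbered 1082 (independence 361.9, divided controls from 390 to 750). CXCL10 and OASL were among the shared increases, UGT3A2 and MRAP among the shared decreases, and 0 genes passed in opposite directions.

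Between CCLE (5 arrays) and SCLE (10 arrays), B cell and plasma cell markers (5 of 14 higher in CCLE), stressed keratinocyte genes (0 of 16) and plasmacytoid dendritic cell markers (0 of 8) were higher as lists in CCLE. With an estimated correlation these calls were lost (adjusted p = 0.0989, adjusted p = 0.473 and adjusted p = 0.371). The mean of B cell and plasma cell markers per array was 11.75 (SD 0.46) in CCLE and 10.18 (SD 0.64) in SCLE, a difference of 1.56 (exact permutation test, two-sided, p = 0.000999, adjusted p = 0.0340), and 3 of 5 CCLE arrays lay above every SCLE array. T cell markers did not pass the same test (difference 0.33, exact permutation p = 0.414, adjusted p = 0.671). Of 15198 genes 56 passed, 28 higher and 28 lower in CCLE, and 2494 had an unadjusted p under 0.05. The larger increases were MYH13 (3.07), PAX5 (2.80), TMPRSS11D (2.74), SIGLEC14 (2.72), SLC13A5 (2.67), CNTNAP2 (2.36), S100A12 (2.33) and MZB1 (2.23) (adjusted p from 0.00950 to 0.0377). The larger decreases were ANGPTL5 (-2.25), ALKAL2 (-2.15), CYP4B1 (-1.98), GRIK2 (-1.91), OR5P2 (-1.84), WNK2 (-1.70), VIT (-1.67) and KCNK4 (-1.67) (adjusted p from 0.00394 to 0.0474). In SCLE PAX5 was above background in 1 of 10 arrays, TMPRSS11D in 2 and MYH13 in 4, and OR5P2 was in 2 of 5 CCLE arrays. PAX5 is the identity factor of B cells, and MZB1 serves antibody secretion.

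B cell and plasma cell markers (14 measured, 5 higher, 0 lower and 9 not passed, median 1.79, adjusted p = 1.29e-11) were higher as a list, with PAX5 and FCRL5 (2.03, adjusted p = 0.0250). B cell and plasma cell markers had 13 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.0989. Plasmacytoid dendritic cell markers were higher as a list (8 measured, 0 higher, 0 lower and 8 not passed, median 1.07, adjusted p = 1.81e-05). Of the plasmacytoid dendritic cell markers, 5 were higher and 0 lower adjusted over the list alone, and with an estimated correlation adjusted p = 0.371. Stressed keratinocyte genes were higher as a list (16 measured, 0 higher, 0 lower and 16 not passed, median 0.93, adjusted p = 1.23e-05). Stressed keratinocyte genes had 5 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.473. Type I interferon-stimulated genes were slightly higher (33 measured, 2 higher, 0 lower and 31 not passed, median 0.39, adjusted p = 3.57e-06), with USP18 (1.23) and HERC5 (1.44) past the threshold. Of the type I interferon-stimulated genes, 2 were higher and 0 lower adjusted over the list alone, and with an estimated correlation adjusted p = 0.473. Monocyte and macrophage markers were also higher as a list (18 measured, 0 higher, 0 lower and 18 not passed, median 0.19, adjusted p = 0.0467). Monocyte and macrophage markers had 0 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.510. Tubular injury genes were higher as a list (15 measured, 0 higher, 0 lower and 15 not passed, median 0.64, adjusted p = 0.0270). Tubular injury genes had 0 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.474. Melanocyte markers were lower as a list (9 measured, 0 higher, 0 lower and 9 not passed, median -0.64, adjusted p = 0.000391). Melanocyte markers had 0 higher and 3 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.473. Erythrocyte markers were lower as a list (7 measured, 0 higher, 0 lower and 7 not passed, median -1.06, adjusted p = 0.0174). Erythrocyte markers had 0 higher and 2 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.473. Cytosolic ribosomal protein genes were lower as a list (23 measured, 0 higher, 0 lower and 23 not passed, median -0.11, adjusted p = 0.0270). Cytosolic ribosomal protein genes had 0 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.586. Of the 9 lists, 0 passed with an estimated correlation. By permutation of the arrays, 3 list means passed: B cell and plasma cell markers, plasmacytoid dendritic cell markers (difference 1.06, exact permutation p = 0.00433, adjusted p = 0.0491) and erythrocyte markers (difference -0.84, exact permutation p = 0.00333, adjusted p = 0.0491).

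Named genes that did not pass between CCLE and SCLE included IFI44L (0.30), MX1 (-0.12), IFI27 (0.25), CXCL9 (-0.06), CXCL10 (0.55), CD8A (0.86), GZMB (0.98), FASLG (0.20), C1QB (0.61) and IL18 (-0.02) (adjusted p from 0.244 to 0.967). A difference in them is not excluded, since on simulated data with each group's own spread this comparison recovered 41.8% of changes of 1. The lists that did not pass, with median and adjusted p, were interferon-gamma response genes (0.24, 0.158), MHC class II genes (-0.01, 0.699), cytotoxic lymphocyte markers (0.34, 0.182), T cell markers (0.38, 0.267), neutrophil markers (0.27, 0.158), mast cell markers (0.15, 0.795) and endosomal Toll-like receptor pathway (0.22, 0.0985). Nor did the other 18 (medians from -0.34 to 0.34, adjusted p from 0.0651 to 0.877) pass. Median, mean and test differed in sign for 5 lists. The count of genes was unstable: leaving out 1 array in turn gave from 5 (without CCLE 3) to 96 (without SCLE 6), and the share above background as a covariate left 6.

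In lupus nephritis (14 arrays) type I interferon-stimulated genes (26 of 32 measured), MHC class II genes (9 of 10) and matrix genes (16 of 20) were higher, and immediate early genes (12 of 17) lower, than in control kidney (7 arrays). With an estimated correlation the calls of all 4 lists were lost (adjusted p = 0.938 for each of the higher lists and adjusted p = 0.147 for the immediate early genes). Against random lists of like level, the interferon-stimulated genes lay above the central 95% in 7 of 7 control arrays and the immediate early genes below it in 7 of 7, whereas MHC class II genes lay above it in 5 of 7 and matrix genes in 1 of 7. The type I interferon-stimulated genes averaged 12.76 (SD 0.51) per array in nephritis and 10.17 (SD 1.18) in control kidney, a difference of 2.59, and all 14 nephritis arrays lay above every control array, by 11.65 against 11.62 at the closest (exact permutation test, two-sided, p = 8.6e-06, the smallest it can give, adjusted p = 5.85e-05). The immediate early genes averaged 11.06 (SD 0.35) and 12.45 (SD 0.71), a difference of -1.39 (exact permutation p = 7.74e-05, adjusted p = 0.000239), and 9 of 14 nephritis arrays lay below every control array. Of 14525 genes, 9427 passed, 7279 higher and 2148 lower, so that 77.2% of the calls went up. The median log2 fold change over all genes was 0.99, a shift that goes with the low share of probes above background in 6 of the 7 control arrays. Without those arrays the median was 0.03 and 1147 genes passed (678 higher, 469 lower), with kidney control 6 alone as the control, assumed to vary like the nephritis arrays. That array correlated with the nephritis arrays at a median r of 0.89 and with its own group at 0.41, the lowest of all 46 arrays, and had the highest interferon mean of the controls (11.62), and every kidney value without the low arrays rests on it. On simulated data with each group's own spread, 278 of 348 genes called in this comparison had no change, so its number of genes is not a measure of the disease effect.

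Type I interferon-stimulated genes in nephritis (32 measured, 26 higher, 1 lower and 5 not passed) had a median log2 fold change of 3.10, which is 2.11 above the median of all genes (adjusted p = 0.00471). Of the type I interferon-stimulated genes, 28 were higher and 1 lower adjusted over the list alone, and with an estimated correlation adjusted p = 0.938. Without the 6 low control arrays the median was 0.97, 0.94 above that of all genes, with 7 of 32 higher (adjusted p = 2.24e-05, range over the alternatives 2.24e-05 to 0.938). SIGLEC1 (5.38, adjusted p = 1.62e-08), a macrophage receptor induced by interferon, IFI44L (5.62) and IFIT2 (3.38) were among them, and SIGLEC1 and IFIT2 were above background in 1 of 7 control arrays and IFI44L in 2. MHC class II genes (10 measured, 9 higher, 0 lower and 1 not passed, median 2.29, adjusted p = 0.0400) rose with HLA-DPB1 (2.34), above background in 1 of 7 control arrays, and CD74 (1.86). MHC class II genes had 9 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.938. Without the low arrays their median was 0.65 and 1 of 10 was higher (adjusted p = 0.0454, range over the alternatives 0.00541 to 0.938). Extracellular matrix genes (20 measured, 16 higher, 0 lower and 4 not passed, median 2.19, adjusted p = 0.0425) rose with LOX (2.44) and SPARC (4.20), above background in 1 and 2 of 7 control arrays, and their median without the low arrays was 0.81 (adjusted p = 0.00572, range over the alternatives 0.00572 to 0.938). Extracellular matrix genes had 16 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.938. Immediate early genes, which respond within minutes to stimulation or tissue handling, fell (17 measured, 0 higher, 12 lower and 5 not passed, median -1.26, adjusted p = 3.53e-09), with ZFP36 (-3.23) and IER2 (-2.72). Immediate early genes had 0 higher and 12 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.147. They moved against the overall shift, and without the low arrays their median was -1.80 with 9 of 16 lower (adjusted p = 8.70e-10, range over the alternatives 7.15e-10 to 0.147).

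Of the genes named beforehand, CXCL10 rose by 2.29, CD8A by 1.57, GZMB by 2.27, C1QB by 2.69, MX1 by 3.22, IFI27 by 4.00 and the proximal tubule transporter SLC34A1 by 1.60 on the log2 scale (adjusted p from 0.000242 to 0.0419). Of these, GZMB was above background in 1 of 7 control arrays, CXCL10 and CD8A in 2 and IFI27 in 3. Without the 6 low control arrays IFI27 (-0.04), GZMB (-0.37) and SLC34A1 (-0.02) changed sign. FASLG was not above background in any of the 7 control arrays and was at least 0.57 higher on the log2 scale in nephritis (adjusted p = 0.000396), whereas IL18 did not pass (0.38, adjusted p = 0.183) and CXCL9 did not pass the filter. By size alone, WDR82 (5.91), TOR1AIP1 (5.78), SNORA8 (5.75), IKZF5 (5.71), IFI44L (5.62), ICE2 (5.54), RAPH1 (5.49) and SRP72 (5.45) rose most (adjusted p from 2.54e-08 to 1.79e-06). EXOSC9 (-3.92), DUSP2 (-3.83), MIR320A (-3.82), ING1 (-3.77), RBFOX1 (-3.73), ELF5 (-3.71), ZNF585B (-3.69) and PADI2 (-3.68) fell most (adjusted p from 3.98e-08 to 1.21e-05). Each of the 8 largest increases was above background in 1 or 2 of the 7 control arrays, and ELF5 in 1 of 14 nephritis arrays. Other probes went up for ING1 (0.74, and 1 down by 0.53), RBFOX1 (1.02 and 0.88), ELF5 (0.42) and ZNF585B (2.52). These falls thus depended on the probe. Without the low arrays WDR82, IKZF5, IFI44L, ICE2, RAPH1 and DUSP2 remained past the threshold in the same direction, and SRP72 (-0.02), EXOSC9 (0.06) and RBFOX1 (0.03) changed sign.

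Of the 34 lists 4 passed, 3 upwards and 1 downwards, and 0 with an estimated correlation. That test sets a list against all other genes, which here rose as a whole, so lists with many members higher did not pass: interferon-gamma response genes (18 of 20 higher, median 2.20, adjusted p = 0.0572), cytotoxic lymphocyte markers (10 of 15 higher, median 1.26, adjusted p = 0.634), T cell markers (12 of 19 higher, median 1.34, adjusted p = 0.314) and B cell and plasma cell markers (9 of 14 higher, median 1.27, adjusted p = 0.235). Nor did monocyte and macrophage markers (13 of 18 higher, median 1.68, adjusted p = 0.224), Fas and death receptor apoptosis genes (7 of 12 higher, median 1.25, adjusted p = 0.265), inflammasome genes (9 of 12 higher, median 1.97, adjusted p = 0.299) and complement genes (10 of 15 higher, median 2.19, adjusted p = 0.235) pass. Nor did proximal tubule markers (12 of 19 higher, median 1.47, adjusted p = 0.408), tubular injury genes (10 of 15 higher, median 1.38, adjusted p = 0.270) and cell cycle genes (9 of 14 higher, median 1.28, adjusted p = 0.314) pass. These medians carry the overall shift: without the low arrays those of interferon-gamma response genes, cytotoxic lymphocyte markers and proximal tubule markers were 0.87, 0.90 and 0.27, and with the covariate 0.61, 0.58 and -0.04. The rest, with median and adjusted p, were plasmacytoid dendritic cell markers (0.78, 0.866), neutrophil markers (1.56, 0.918), mast cell markers (0.92, 0.866), endosomal Toll-like receptor pathway (0.74, 0.965), basal keratinocyte markers (1.46, 0.634), differentiated keratinocyte markers (0.88, 0.780) and stressed keratinocyte genes (-0.76, 0.387). Nor did hair follicle markers (0.47, 0.866), sweat and sebaceous gland markers (-0.19, 0.206), melanocyte markers (0.48, 0.950), adipocyte markers (0.50, 0.387), endothelial markers (1.74, 0.565), smooth and striated muscle markers (1.87, 0.872) and podocyte markers (-0.06, 0.174) pass. Nor did thick ascending limb and distal tubule markers (0.94, 0.866), collecting duct markers (0.49, 0.299), oxidative phosphorylation genes (0.51, 0.866), cytosolic ribosomal protein genes (0.80, 0.387) and erythrocyte markers (0.01, 0.265) pass. For 13 lists the median, mean and test differed in sign, most often a positive median with a test that went down. By permutation of the arrays 24 list means differed, 23 higher and 1 lower, the immediate early genes.

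**Figure D3:**
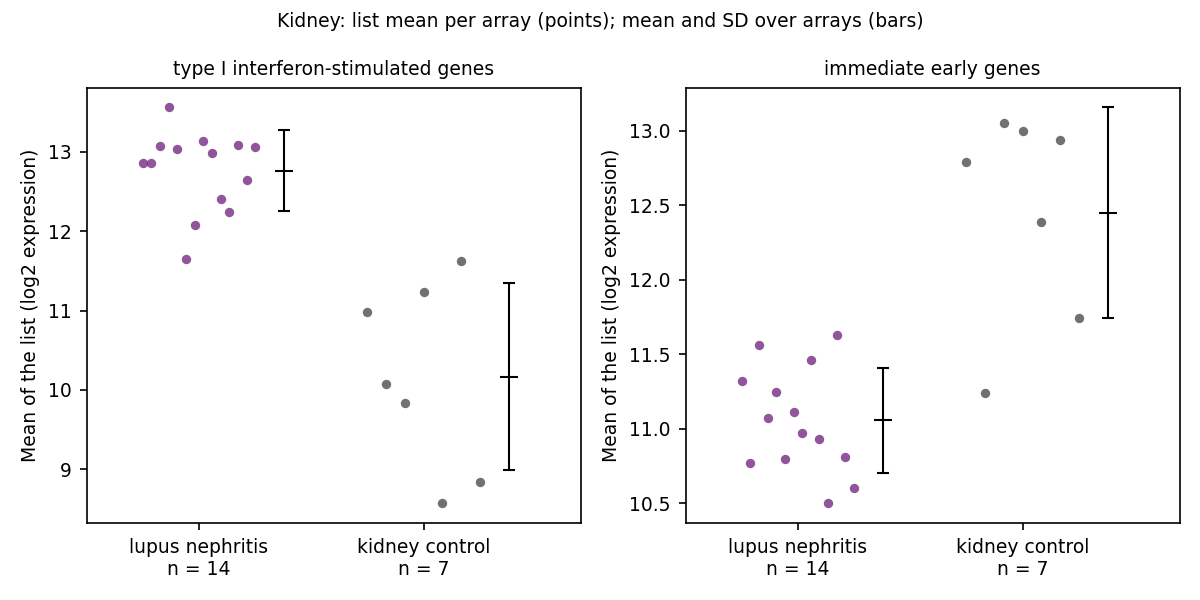
Mean log2 expression of type I interferon-stimulated genes and of immediate early genes (vertical axes) per kidney array, by group, with 1 point per array and bars for the mean and SD over arrays. Nephritis and control kidney average 12.76 and 10.17 for the interferon-stimulated genes and 11.06 and 12.45 for the immediate early genes.

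The lupus effect in kidney and that in skin (the mean of CCLE and SCLE against control skin) were set against each other in 1 fit over all 46 arrays. Immediate early genes (13 of 17 measured), cytotoxic lymphocyte markers (2 of 14) and plasmacytoid dendritic cell markers (4 of 6) had lower effects in kidney, and extracellular matrix genes (18 of 20) higher ones. With an estimated correlation the calls of these 4 lists were lost (adjusted p from 0.0976 to 0.956). Of 13988 genes, 9201 had an effect that differed, 7192 higher in kidney and 2009 lower, with a median difference of 1.17. Without the low arrays the median was -0.01 and 270 differed (158 higher, 112 lower). BST2, an interferon-stimulated gene that tethers viruses, had a lower value in nephritis (kidney -2.85, skin 1.95, difference -4.79, SE 0.30, adjusted p = 2.71e-16). MAFF (kidney -3.61, skin 1.39), LCE3A (kidney -2.89, skin 3.03), EXOSC9 (kidney -3.92, skin 0.58) and B3GNT3 (kidney -3.06, skin 1.24) were the other largest negative differences. CAPN13 (kidney 3.52, skin -3.46), FADS1 (kidney 4.22, skin -2.57), TLCD4 (kidney 3.74, skin -3.04), CLSTN2 (kidney 4.70, skin -1.92) and WDR72 (kidney 4.35, skin -2.26) were the largest positive ones (adjusted p from 2.71e-16 to 1.21e-06 over the 10 genes). CAPN13, FADS1 and TLCD4 were above background in 1 of 7 control kidney arrays and CLSTN2 in 2, and LCE3A was in 1 of 14 nephritis arrays. BST2 and MAFF passed without the low arrays as well.

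As a list, immediate early genes had lower effects in kidney (17 measured, 0 higher, 13 lower and 4 not passed, median -1.29, adjusted p = 9.60e-09). Immediate early genes had 0 higher and 13 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.0976. Cytotoxic lymphocyte markers had lower effects as a list (14 measured, 0 higher, 2 lower and 12 not passed, median -0.78, adjusted p = 0.0188). Cytotoxic lymphocyte markers had 0 higher and 2 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.956. So had plasmacytoid dendritic cell markers (6 measured, 0 higher, 4 lower and 2 not passed, median -1.19, adjusted p = 0.0273). Of the plasmacytoid dendritic cell markers, 0 were higher and 4 lower adjusted over the list alone, and with an estimated correlation adjusted p = 0.867. Extracellular matrix genes (20 measured, 18 higher, 0 lower and 2 not passed, median 2.41, adjusted p = 0.0108) had higher effects. Extracellular matrix genes had 18 higher and 0 lower members adjusted over the list alone, and with an estimated correlation adjusted p = 0.956. Their median lay 1.24 above that of all genes, 1.32 without the low arrays and 1.13 with the share above background as a covariate. Type I interferon-stimulated genes did not pass (32 measured, 17 higher, 6 lower and 9 not passed, median 1.34, adjusted p = 0.489). Of the type I interferon-stimulated genes, 17 were higher and 6 lower adjusted over the list alone. Their median was 0.17 above that of all genes, and without the low arrays it was -0.58 (adjusted p = 2.19e-08, range over the alternatives 2.19e-08 to 0.959), so the direction depended on the low arrays, which include 3 of skin. The remaining 29 lists had adjusted p from 0.131 to 0.915. Median, mean and test differed in sign for 14 lists.

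Genes higher in both tissues, by the same fit, numbered 657 of 1333 higher in skin and 8168 higher in kidney, fewer than the 778.4 that independence gives (Fisher's exact test across genes, two-sided, p = 2.09e-12). Genes lower in both numbered 202 of 1135 and 2125 (independence 172.4, Fisher's exact test p = 0.0123). Without the low arrays the overlaps were 200 higher (independence 84.3) and 153 lower (independence 71.8), more than independence gives. That setting also left out SCLE 8, SCLE 10 and skin control 5. With all arrays kept, separate fits per tissue gave 1545 higher in both (independence 1504), no filter 622 (623.7) and the covariate 282 (174.3). The excess of lower genes held with the covariate (278, independence 166.6) and the strict filter (178, 109.5). Separate fits (355, 460.8), no filter (212, 219.9) and array weights (136, 231.6) lost it, and SCLE alone gave 230 (220.9, Fisher's exact test p = 0.487). Both overlaps therefore depended on the processing, and the cause was not tested. IFI44L, MX1, IFI27, CXCL10, GZMB, CD8A and C1QB rose in CCLE, SCLE and nephritis in separate comparisons. In kidney IFI27, GZMB and MX1 reversed in an alternative, and most named genes lost their call or changed sign without low arrays.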

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

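The tests chosen after the result was seen were those of the overall kidney shift, of the interferon, MHC class II and matrix lists in kidney, of the label of kidney control 6, and of array share and lymphocyte number behind the B cell markers. Single arrays stood apart from the rest of their group (a gap to the nearest other array above the 95% critical value of Dixon's test) in 40 of 343 groups of values. The 14 lupus nephritis arrays were not tested, since the test covered groups of 4 to 10 arrays. Chance gives about 1 in 20 groups, here 17.2. As log2 values of the array that stood apart, these were, in CCLE, C1QC in CCLE 3 (15.23), CIITA in CCLE 4 (11.72), HLA-DOB in CCLE 4 (14.16), KRT25 in CCLE 4 (9.05), SLC13A5 in CCLE 4 (9.36), LPL in CCLE 5 (8.66), MITF in CCLE 5 (10.84) and POU2AF1 in CCLE 5 (11.97). In SCLE they were PLAC8 in SCLE 3 (10.20), PAX5 in SCLE 6 (11.25), AWAT2 in SCLE 7 (11.77), CAPN13 in SCLE 7 (11.46), C2 in SCLE 9 (13.22) and CPA3 in SCLE 10 (7.47). In control skin they were HLA-DPA1 in skin control 1 (13.78), CCL5 in skin control 2 (13.78), PTCRA in skin control 2 (8.88), LGR5 in skin control 4 (9.88), CXCL11 in skin control 5 (8.63), CXCL9 in skin control 5 (9.82), KLHDC7B in skin control 5 (10.83), AWAT1 in skin control 6 (7.96), GRIK2 in skin control 6 (12.21), PAX5 in skin control 7 (7.75) and FCRL5 in skin control 10 (8.55), with 3 interferon-induced genes in 1 array, skin control 5. Kidney control 6 stood apart in 14 genes, EXOSC9 (8.63), FASLG (7.51), GZMB (10.26), HLA-DPB1 (8.09), ICE2 (12.29), IFIT2 (10.40), IKZF5 (13.40), LOX (8.52), MIR320A (8.25), RBFOX1 (8.21), SIGLEC1 (10.80), SRP72 (13.62), TOR1AIP1 (13.85) and WDR82 (12.63), and kidney control 4 in CXCL10 (11.71).

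Differences between groups of patients under the same contrast were tested directly. Between CCLE and SCLE 56 genes differed, among them, as log2 differences, MYH13 (3.07), PAX5 (2.80), TMPRSS11D (2.74), SIGLEC14 (2.72), SLC13A5 (2.67), CNTNAP2 (2.36), S100A12 (2.33), MZB1 (2.23), ANGPTL5 (-2.25), ALKAL2 (-2.15), CYP4B1 (-1.98), GRIK2 (-1.91), OR5P2 (-1.84), WNK2 (-1.70), VIT (-1.67), KCNK4 (-1.67), USP18 (1.23), HERC5 (1.44) and FCRL5 (2.03). Between the lupus effects in kidney and skin 9201 genes differed, among them CAPN13 (6.97), FADS1 (6.79), TLCD4 (6.78), CLSTN2 (6.62), WDR72 (6.61), LCE3A (-5.92), MAFF (-5.00), BST2 (-4.79), EXOSC9 (-4.51) and B3GNT3 (-4.29).

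The excess of higher genes in lupus nephritis over control kidney may come from weak signal in the control arrays. The median over genes of the nephritis mean minus kidney control 6, the control array with a usual share of probes above background, was 0.0263, against 0.99 with all 7 control arrays. Kidney control 6 was more like the nephritis arrays (median r 0.89) than its own group (0.41). Its usual signal among weak arrays could give that, untested. Its immediate early mean (12.94) lay among the other controls (11.24 to 13.05), 5.36 SD above the nephritis mean (arrays 10.5 to 11.63). That list was picked after the result and may follow handling, so a nephritis sample or another kind stays open. Over the 7 control arrays that median fell as the share above background rose (Spearman rho -0.964, exact permutation p = 0.00278, Pearson r -0.935, exact permutation p = 0.00476, and r -0.918 without the 2 arrays farthest from the median share). By median difference, type I interferon-stimulated genes lay above the central 95% of 10000 random lists of like level in 7 of 7 control arrays. Immediate early genes lay below that range in 7 of 7. Such lists ignore correlation between genes, so weak signal acting by gene level is argued against for both, not excluded. For the other lists it stays open. The MHC class II genes lay above that range in 5 of 7. The extracellular matrix genes lay above it in 1 of 7, kidney control 6, where signal was not weak (0.815 against -0.276 to 0.44), and within it in the weak arrays, where it was wide (0.916 to 4.16 in kidney control 5). Tissue handling and the disease itself stay open, as untested.

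More B cell and plasma cell transcripts in CCLE than in SCLE were not accounted for by the share above background, since with the share as a covariate the list's median was 1.51 (adjusted p = 1.69e-16, range over the alternatives 1.69e-16 to 0.0989). T cell markers differed less. The B cell and plasma cell mean minus the T cell mean differed by 1.24 (exact permutation p = 0.00266). It was 0.21 (SD 0.50) in CCLE, -1.02 (SD 0.67) in SCLE and -0.67 (SD 0.53) in control skin. More lymphocytes of other kinds was not tested. A hypothesis is that CCLE lesions hold a larger B lineage share. Differences in biopsy site or lesion age, which were not analysed here, could produce the same.

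More genes passed for SCLE (7344) than for CCLE (2926). Over 100 draws of 5 of the 10 SCLE arrays the median count was 5787 (lowest 2760, highest 7875). Only 1 draw gave 2926 or fewer. CCLE had 3776 (SCLE 6985) with only the groups compared and 5821 (SCLE 8098) with array weights, so array number stays open. A smaller true effect in CCLE is not shown, since its interferon list had the larger median (2.06 against 1.57).

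Other splits of the arrays into groups of the same sizes were run, 100 per comparison with the real one. In the main fit it gave the most genes each time. CCLE had 2926 against a highest other of 993, SCLE 7344 against 1326 and CCLE against SCLE 56 against 15. Nephritis had 9427 against 3506, and the difference between tissues 9201 against 6932. There weak signal could give this, as all weak kidney arrays were controls. For list counts in camera, another split tied with the real one for SCLE (2 of 100, 21 against 21), so chance is not excluded. It cannot be excluded for CCLE (9 of 100, 22 against 23), CCLE against SCLE (35 of 100, 9 against 19), nephritis (42 of 100, 4 against 15) or the difference between tissues (54 of 100, 4 against 17). Other splits passed a median of 15 of the 34 lists for CCLE, 7 for SCLE, 6 for CCLE against SCLE, 3 for nephritis and 4 for the difference between tissues, so a list call at the preset correlation is weak evidence.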

How the results depend on the processing

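Alternatives chosen after the data had been seen were quantile normalization, separate fits per tissue, leaving out SCLE 8 to 10, all settings for the likeness of CCLE and SCLE, the overlap settings other than CCLE or SCLE alone, permutation of list means, lists without low arrays or with the replicate block, and named genes with 1 array left out. Planned but not run were neqc over all arrays, no background correction and slide as a block, since scanner values per sample were not used here. Array weights gave 5821 genes for CCLE against control (2926 in the main setting), 4579 for CCLE against SCLE (56), 5273 for nephritis (9427) and 5271 for the difference between tissues (9201). A log2 fold change of at least 1 left 1667 genes for CCLE and 2847 for SCLE. For CCLE against SCLE every probe gave 87 genes, the share as a covariate 6, no low arrays (SCLE 8, SCLE 10 and skin control 5 left out) 20, the replicate block 11, only the groups compared 3 and no SCLE 8 to 10 23. For nephritis the covariate gave 1290 (714 higher, 576 lower, median of all genes -0.14), no low arrays, with kidney control 6 as the only control and assumed to vary like the others, 1147 and the replicate block, paired by number, 5669. For the difference between tissues the covariate gave 2245 and no low arrays 270. Quantile normalization moved the median of all genes in kidney from 0.99 to 0.66 (8915 genes, 67.2% higher). The replicate block gave 3194 genes for CCLE and 7746 for SCLE, but the labels give no pairing, and in no comparison was every r between samples of the same number above 0.1. For CCLE and control skin 4 of 5 pairs were (median r 0.31), and the own number was the best match for 3 of 5, a hint from the data that some numbers go together. The values were 5 of 10 pairs for SCLE and control skin (median r 0.095, own number best for 2), 2 of 5 for CCLE and SCLE (0.026, 1) and 2 of 7 in kidney (0.029, 2). Lists past the threshold fell from 22 to 9 in CCLE, and from 21, 9, 4 and 4 to 0 in the other comparisons, with an estimated correlation. For CCLE against SCLE 17 lists passed with the covariate, 14 without low arrays and 14 without SCLE 8 to 10, and for the difference between tissues 9 without low arrays. The overlap of higher genes was 657, with 282 under the covariate (independence 174.3), 200 without low arrays, 296 with CCLE alone (independence 313.6) and 1545 in separate fits (independence 1504). The overlap of lower genes was 202, with 77 for CCLE alone (independence 53.8) and 355 in separate fits (independence 460.8). Leaving out 1 array in turn gave 1831 (without CCLE 6) to 3409 (without skin control 6) genes for CCLE, with 1855 without CCLE 4. It gave 6647 to 7825 for SCLE, 8608 to 10246 for nephritis and 8770 to 9865 for the difference between tissues. For CCLE against SCLE it gave 5 (without CCLE 3) to 96 (without SCLE 6), with 12 without CCLE 2 and 28 without CCLE 6. The covariance of CCLE and SCLE effects (0.487) was 0.374 with no filter, 0.421 with array weights and 0.428 to 0.542 with 1 array left out. Named genes of CCLE (65 of 65) and SCLE (64 of 64) against control skin kept direction and call under array weights, the covariate and without low arrays. For CCLE against SCLE 17 of 29 lost their call with the covariate and 15 of 29 without low arrays, and under array weights 28 were the same and 1 newly passed. In kidney, without low arrays, 10 were the same, 16 lost their call and 6 changed sign: SRP72 (-0.0170), EXOSC9 (0.0601), RBFOX1 (0.0332), IFI27 (-0.0416), GZMB (-0.37) and SLC34A1 (-0.0211). With the covariate MX1 (-0.42), IFI27 (-0.31) and SLC34A1 (-0.39) changed sign. ELF5 changed sign with quantile normalization (0.10), and when kidney control 1, 2, 3, 4, 5 or 7 or nephritis 9 was left out (0.28 to 0.80), where its probe failed the filter and another stood in. Over all 21 arrays left out ELF5 ranged from -4.34 to 0.80. Under the strict filter 1 of the 65 and 3 of the 64 skin genes were not measured. PADI2 in kidney and LCE3A in the difference between tissues gave no value without low arrays. In camera without low arrays the endosomal Toll-like receptor list turned up in nephritis (adjusted p = 0.0282, range over the alternatives 0.0282 to 0.991) and the erythrocyte list turned up in the difference between tissues (adjusted p = 0.0322, range over the alternatives 0.0322 to 0.959). The cause of the other movements was not tested. Signal over background limits the kidney comparison, where SRP72 was 5.45 higher with all arrays and -0.02 without the low ones, and the median of the type I interferon-stimulated genes 3.10 and 0.97.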

Other observations

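Among the 14 lupus nephritis arrays, the mean of the type I interferon list rose with that of monocyte and macrophage markers (Pearson r 0.780, permutation p = 0.00140, Spearman rho 0.811, permutation p = 0.00087, adjusted p = 0.00522 over 6 relations, and r 0.83 without the 2 arrays farthest from the median). It rose as well with B cell and plasma cell markers (r 0.565, permutation p = 0.0362, rho 0.732, permutation p = 0.00394, adjusted p = 0.0118, r 0.664 without 2 arrays) and with interferon-gamma response genes (r 0.729, permutation p = 0.00290, rho 0.688, permutation p = 0.00817, adjusted p = 0.0163, r 0.715 without 2 arrays). For plasmacytoid dendritic cell markers rho was 0.604 (permutation p = 0.0255, adjusted p = 0.0382, r 0.529, permutation p = 0.0519, r 0.678 without 2 arrays). Over all 33 other lists rho ranged from -0.688 (thick ascending limb and distal tubule markers) to 0.811 (macrophage markers), with a median of 0.275. The interferon list holds the macrophage receptor SIGLEC1, so part of the 0.811 may be built in. Among the 10 SCLE arrays the same 6 relations gave rho from -0.248 to 0.455 and adjusted p = 0.837 each. None of these relations involves the weak control kidney arrays. The difference between nephritis and SCLE was not tested.

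A hypothesis is that interferon-stimulated transcripts in nephritis vary with the amount of immune infiltrate. With T cell markers rho was 0.574 (permutation p = 0.0352, adjusted p = 0.0423, r 0.402, permutation p = 0.153, r 0.517 without 2 arrays), above the 0.5 set beforehand, although r alone did not pass. The share of probes above background, which varied little among these arrays (43.4% to 45.7%), did not account for the spread, since rho with it was -0.209 (permutation p = 0.475, r -0.183, permutation p = 0.530, r -0.307 without 2 arrays). Other measures of array quality were not tested. A larger share of infiltrate would also lower tubular transcripts, and the negative rho of distal tubule markers may reflect that, as for collecting duct markers (-0.512). How much of each biopsy was cortex or medulla could produce the same.

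BST2 went against the other interferon-stimulated genes in kidney. It averaged 8.76 (SD 0.30) in 14 nephritis arrays and 11.61 (SD 0.78) in 7 control arrays, with every nephritis array below every control array (highest 9.21 against lowest 9.91), while it rose in CCLE (2.29) and SCLE (1.60). Without the low arrays, which leaves 1 control kidney array, the difference between tissues was -3.06 (adjusted p = 2.92e-05). BST2 was singled out after its values were seen. A probe that also binds another kidney transcript could give this, and was not tested.

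The column of CCLE replicate 1 holds values from 0 to 1, read here as detection p-values from the values alone. On that reading 18317 of 47303 probes (38.7%) had p under 0.05. Among 15198 genes tested in skin 12425 were detected in this sample, and among 33 type I interferon-stimulated genes 32 were. The sample entered no comparison.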
